A study of Citrus reticulata with 36 samples.

How the data were processed

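Ovules of the mandarin-type citrus ponkan (Citrus reticulata) were profiled by RNA sequencing in 2 cultivars, "Huagan No.4" (HG) and "Egan No.1" (EG). In each cultivar 2 ovule tissues were isolated by laser capture microdissection, in which chosen cells are cut from a tissue section under a microscope: the nucellus, the central tissue of the ovule that surrounds the embryo sac, and the integument, the outer layer that becomes the seed coat. Tissue was taken at 18, 28 and 32 days after pollination (DAP), with 3 biological replicates stated for each of the 12 groups, which gave 36 libraries. Per the labels' protocols, nanogram amounts of total RNA were reverse transcribed with random primers and amplified as cDNA (Ovation RNA-seq V2, a single-primer isothermal amplification), and the paired-end libraries were sequenced on instruments of 2 Illumina models. Which instrument read which library is not given in the sources used here, so a difference between instruments could not be tested. The labels do not tie a captured region to a tree, fruit or ovule, nor say how regions were chosen, so regions of a group may share a tree or fruit. In that case the p-values below, which measure the spread between these samples, are too small.

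The authors deposited a table of read counts per gene identifier and a table of FPKM values (fragments scaled to gene length and sequencing depth) with the same rows and columns. The deposited counts are whole numbers and were used as deposited. The deposited FPKM values are rounded by the authors and served for an alternative test and for gene lengths. Per the submitters' processing notes, cutadapt, Bowtie2, RSEM and DESeq were used; their versions, settings and roles, and the genome build, annotation or assembly, are not given in the sources used here. RSEM gives estimated counts, and whether these were rounded before deposit is not given either. All columns were matched to samples by cultivar, tissue, stage number and replicate number. The columns number the stages 1 to 3, and these numbers were read as 18, 28 and 32 DAP in order of time, which no label states; were that reading wrong, every stage named here would change with it.

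The table held 128861 gene identifiers, of which 34664 had no count in any library. The identifiers carry no gene name, description or sequence, and no table pairing them with names was used here. The gene lists fixed in advance could therefore not be matched, no list was tested, and at most 2 identifiers per direction are printed for a comparison. The number of identifiers exceeds what is usual for plant genes, so 1 gene may be split over several identifiers and near-identical copies may share reads. The counts of called genes below are counts of identifiers.

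The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM normalisation. Identifiers were kept by filterByExpr with its groups set to the 12 groups, a minimum count of 10 and a minimum total of 15. This left 57344 identifiers with 99.9% of all counts. A single model with 1 mean per group was fitted to all 36 libraries, with 24 residual degrees of freedom and robust dispersion estimates. The common biological coefficient of variation was 0.439. Each comparison was a contrast of group means, adjusted by the Benjamini-Hochberg method over the identifiers tested, with a threshold of 0.05 on the adjusted p. "Called" below means past that threshold. Cultivar by stage was tested as a joint contrast and cultivar by tissue as a difference of differences. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Levels are given as TMM-normalised CPM (counts scaled to a common library size), with the SD over libraries. Named identifiers are the 2 largest rises and 2 largest falls by fitted fold change among those called, without overlap between the groups (within each stage for a mean of stages) and with at least 5 CPM in the higher group, so every library shows the direction given. Counts of identifiers past 16-fold use the bound described next where a group had 0 counts. Where a group had 0 counts, the fold is a lower bound against 3 counts over that group. Intervals on count ratios are exact 95% intervals and cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

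Total counts lay between 12687779 and 20947644 per library. No 2 libraries of a group were identical. Within groups the chi-square per degree of freedom between libraries was at least 8.41, so every library was counted once. The lowest values were those of EG replicates 2 and 3 at 32 DAP, 8.41 in integument and 10.7 in nucellus. Whether these replicates share material is not given in the sources used here, so they may not be independent. Counts were simulated for 57344 identifiers from a single mean per identifier over all 36 libraries, the real library sizes and the estimated dispersions. Libraries were drawn independently, with 40 identifiers changed for each fold. The comparison of cultivars in integument at 32 DAP then recovered 7.5% of genes raised 2-fold, 50% of those raised 4-fold and 52.5% of those raised 8-fold, with 2 false calls. Falls were recovered less often, 0% of those to 0.5 of the level and 27.5% of those to 0.25. The tissue comparison over the stages of EG recovered 37.5%, 72.5% and 90% of the same rises and 32.5% and 72.5% of the same falls, with 10 false calls. A comparison with no simulated change, cultivars in integument at 28 DAP, gave 0 calls.

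Replicate numbers were checked for pairing through the correlation of deviations from group means. In EG, all 9 same-numbered pairs of nucellus and integument libraries were correlated above 0.1 (lowest 0.223), so the numbers were taken to pair the tissues of EG. This pairing comes from the data and is not stated in the labels. The main fit did not use it and treated these libraries as independent. It entered only the replicate block, 1 of the alternatives below. In HG, 8 of 9 pairs passed (lowest 0.0525), which does not meet the rule. Between cultivars only 5 of 18 same-numbered pairs passed. Before the data were examined, the following alternatives were set: RLE size factors, no filter on low counts, DESeq2 1.42.0, a replicate block, the compared libraries alone, limma 3.58.1 on log2(FPKM + 1) for identifiers with an FPKM of at least 1 in 3 libraries, a minimum fold change, and leaving out each library in turn. Chosen after seeing the data were voom with sample quality weights, a filter at a mean of 5 CPM, removal of a per-library trend on gene length, the omission of 2 libraries that stood apart from all comparisons, the tissue comparisons at single stages and the stage change from 18 to 32 DAP averaged over the cultivars.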

Results

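The series addressed seed abortion in ponkan by comparing the transcriptomes of 2 cultivars, HG and EG, in nucellus and integument captured from ovules at 18, 28 and 32 DAP. Each of the 12 groups held 3 libraries. Total counts ranged from 12687779 to 20947644 per library, and between 55947 and 69127 gene identifiers had at least 1 count in a library. Spearman correlations between libraries of a group were 0.814 to 0.983, with a median of 0.933. The median was 0.924 between HG and EG libraries of the same tissue and stage, and 0.859 between nucellus and integument libraries. The first principal component held 28.3% of the variance and separated the tissues, and the second held 15.5% and spread libraries within groups.

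**Figure D1:**
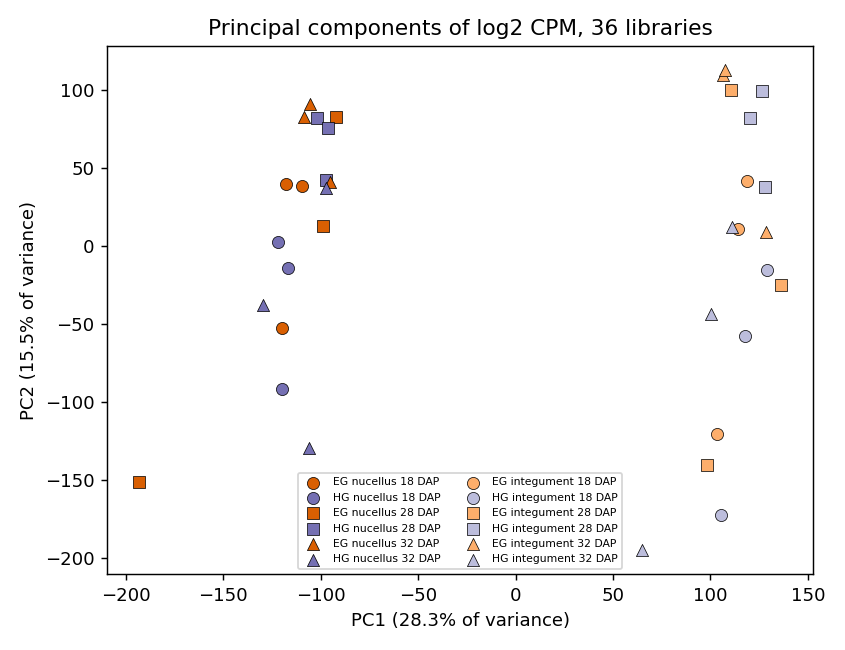
Principal components of log2 CPM for the 36 libraries, with PC1 (28.3% of the variance) on the x axis and PC2 (15.5%) on the y axis. Colours mark cultivar and tissue and symbols mark the stage; the tissues lie apart on PC1, while libraries of 1 group spread along PC2.

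The most abundant identifier, c94721_g1, averaged 55294 ± 16267 CPM in nucellus and 80086 ± 16345 CPM in integument (SD, n = 18 each, library-size CPM). The 10 most abundant identifiers took 7.6% to 33.8% of a library's counts. A set of 21 identifiers varied together over the libraries, each correlated at 0.95 or above with c81185_g1 on the log2 CPM scale. It was chosen after the values were seen. The set took from 1.46% to 34.2% of the counts, with a median of 5.64%, and within a single group its share differed by up to 19.1-fold. The highest share was in replicate 1 of EG nucellus at 28 DAP. In that library, 3.59% of the genes with at least 20 counts in both other replicates had 0 counts, against at most 0.445% in any other library tested in the same way.

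**Figure D2:**
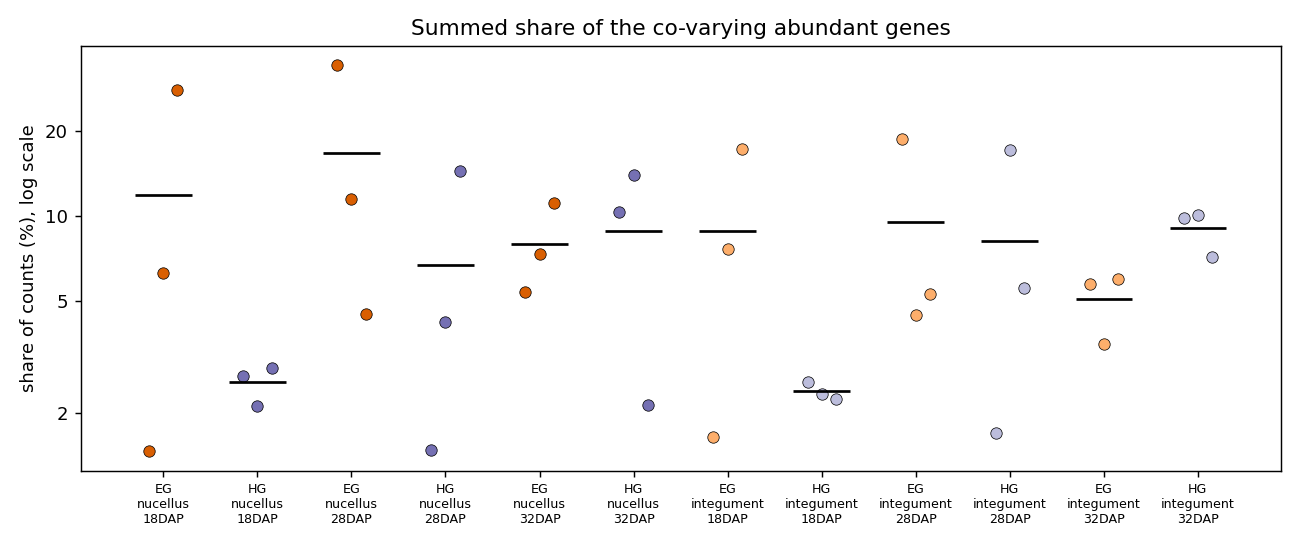
Summed share of counts (%, log scale) of the 21 co-varying abundant identifiers in each of the 36 libraries, by group on the x axis; points are libraries and bars are group means. The share runs from 1.46% to 34.2%, and replicates of 1 group differ by up to 19.1-fold.

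Nucellus and integument differed in a large share of the transcriptome in both cultivars. In EG, averaged over the stages, 5633 identifiers were higher in nucellus and 7639 higher in integument (13272 of 57344 called). In HG the numbers were 5361 and 7510 (12871 called). The identifier c88406_g1 was among the most strongly nucellus-preferring in EG, at 6505 ± 1909 CPM in nucellus and 33.3 ± 28.6 CPM in integument (SD, n = 9 each; log2 fold change 7.71, SE 0.65, edgeR adjusted p = 6.62e-10). Another, c974_g1, averaged 9.84 ± 10.5 CPM in EG nucellus (2.49 to 36.7 CPM in the 9 libraries) and 0.0426 ± 0.0479 CPM in integument. On the integument side of EG, c113787_g1 averaged 8.05 ± 4.40 CPM against 0.0427 ± 0.0761 CPM in nucellus. For c126976_g1, at 5.06 ± 2.78 CPM in EG integument, a single count was found over the 9 nucellus libraries, and the ratio of 841 had a counting interval of 151 to 33255. In HG, c78833_g1 averaged 7.87 ± 6.13 CPM in nucellus and 0.0671 ± 0.140 CPM in integument. In the same cultivar c88114_g1 averaged 6.83 ± 2.95 CPM in integument and 0.0482 ± 0.0638 CPM in nucellus.

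Large differences were more often on the integument side. In EG, 1022 called identifiers were at least 16-fold higher in integument and 315 at least 16-fold higher in nucellus; in HG these numbers were 877 and 354. The cultivars shared 3636 calls on the nucellus side and 5981 on the integument side, where independent lists of these sizes would share 527 and 1000, and none was called in opposite directions. Across genes, which are not independent replicates, the Spearman correlation of the fold changes in EG and HG was 0.745. Of the 2560 identifiers called at least 2-fold higher in EG nucellus, 99.1% were also higher in HG nucellus and 2039 were called there. The test of whether the tissue difference itself differed between cultivars called 0 identifiers with edgeR. At an unadjusted p under 0.05 it had 1641 (2.86%), fewer than independent tests without an effect would give at that threshold. Genes vary together across libraries, so this share alone does not show that an effect is absent. DESeq2 called 2 and voom with sample quality weights called 0. With a mean of at least 5 CPM required, which tests fewer identifiers, the calls were 8171 in EG and 7840 in HG.

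Captured tissue carried little of the transcripts that marked the other tissue. For identifiers at least 32-fold higher in 1 tissue of the other cultivar, the median level in the opposite tissue was 0.151% to 1.78% of their level in the preferred tissue over the 18 integument libraries. In EG nucellus libraries the range was 0.422% to 2.01%, and in HG nucellus libraries it was 1.71% to 3.10%. Genes expressed in both tissues add to these values, and the difference between cultivars was not tested.

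At single stages, the tissue comparison called 3964 identifiers in EG at 18 DAP, 5188 at 28 DAP and 3939 at 32 DAP. In HG it called 4918, 4153 and 3144. Integument-higher calls outnumbered nucellus-higher calls in each of the 6 comparisons, from 2600 against 1364 in EG at 18 DAP to 2113 against 1031 in HG at 32 DAP. In EG, 627 identifiers were called higher in nucellus at all 3 stages and 1473 higher in integument at all 3; in HG these were 508 and 1171. No identifier of EG was called in opposite directions at different stages, and 1 of HG was. DESeq2 gave the same order of the stages, with 5498, 7086 and 5328 in EG and 6781, 5760 and 4807 in HG. Voom with quality weights gave another order, with 5636, 4425 and 14555 in EG and 8093, 10997 and 2502 in HG. Pairing same-numbered nucellus and integument libraries as a replicate block raised the EG calls to 6894, 7892 and 6737. The counts rested partly on single libraries. Without nucellus replicate 2 they were 2298 in EG and 3140 in HG at 18 DAP, 2499 in EG at 32 DAP and 2222 in HG at 28 DAP. At 28 DAP in EG, 2921 were called without nucellus replicate 1 and 3259 without integument replicate 3. Without nucellus replicate 3 the counts were 2526 in EG at 32 DAP, 2672 in HG at 28 DAP and 1584 in HG at 32 DAP.

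**Figure D3:**
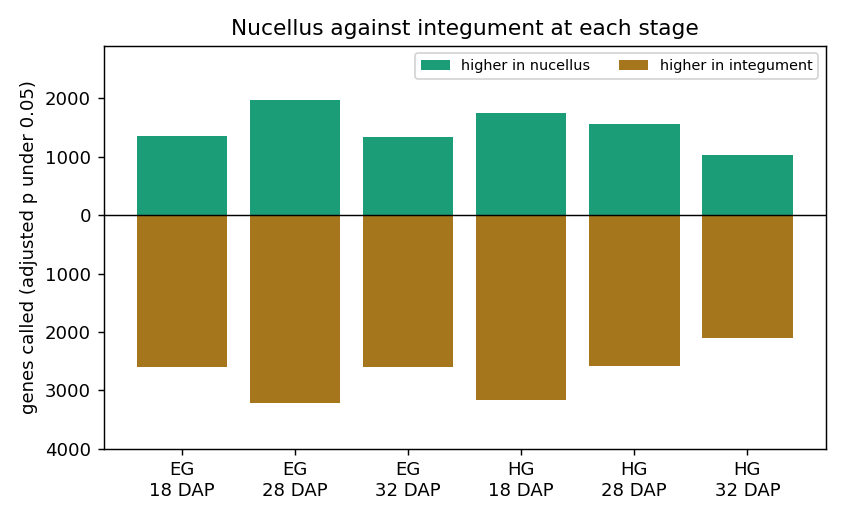
Identifiers called between nucellus and integument (edgeR adjusted p under 0.05) for each cultivar and stage; bars above 0 count those higher in nucellus and bars below 0 those higher in integument. Integument-higher calls are more numerous in all 6 comparisons, for example 3219 against 1969 in EG at 28 DAP.

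Cultivars were compared within each tissue and stage, which asks where HG and EG ovules differ. In nucellus at 32 DAP, edgeR called 29 identifiers higher and 2 lower in HG. DESeq2 called 442, voom with quality weights 1078 and limma on FPKM 88, and edgeR on these 6 libraries alone called 0. Among those that met the naming rule, the largest rise was of c57814_g1, at 44.9 ± 33.9 CPM in HG and 2.06 ± 0.54 CPM in EG (SD, n = 3 each; log2 fold change 4.45, SE 0.78, edgeR adjusted p = 0.0259), and the larger fall was of c68615_g1, at 6.25 ± 4.68 CPM in HG and 56.7 ± 33.0 CPM in EG (log2 fold change -3.17, SE 0.63, edgeR adjusted p = 0.0471). The others named were c120532_g1, at 7.49 ± 4.90 and 0.420 ± 0.219 CPM, and c15909_g1, at 43.3 ± 9.05 and 133 ± 47.4 CPM. At 18 DAP, c6063_g1 alone was called, at 0.781 ± 0.364 CPM in HG and 4.53 ± 1.39 CPM in EG (SD, n = 3 each). EdgeR on the compared libraries alone and edgeR without a filter each gave 0 calls, while DESeq2 called 16, voom 1 and limma on FPKM 7. At 28 DAP edgeR called 0, with 7085 at an unadjusted p under 0.05, while DESeq2 called 544, voom with quality weights 207 and limma on FPKM 21. The 32 DAP calls fell to 0 when EG replicate 2, HG replicate 2 or HG replicate 3 was left out, to 1 without EG replicate 3 and to 5 without EG replicate 1, and rose to 276 without HG replicate 1 and to 146 without replicate 1 of EG nucellus at 28 DAP. The 28 DAP count was 497 without EG replicate 2, 246 without EG replicate 3 and 26 without HG replicate 1, and the 18 DAP call was lost without EG replicate 1 or 3 or HG replicate 2 or 3.

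Averaged over the stages, edgeR called 8 identifiers higher and 1 lower in HG nucellus, while DESeq2 called 362, voom 306 and limma on FPKM 46. Under the naming rule, c119473_g1 averaged 10.1 ± 3.45 CPM in HG and 4.86 ± 1.59 CPM in EG (SD, n = 9 each; log2 fold change 1.06, SE 0.17, edgeR adjusted p = 0.0136). The second, c116660_g1, averaged 25.9 ± 8.51 and 14.4 ± 2.97 CPM. The single fall was of c3908_g1, at 9.28 ± 2.32 CPM in HG and 20.3 ± 7.87 CPM in EG, which was named after its values were seen. With single libraries left out, the count ranged from 1, without replicate 3 of EG nucellus at 32 DAP, of HG nucellus at 18 DAP or of HG nucellus at 32 DAP, to 56 without replicate 1 of EG nucellus at 28 DAP. The values were 3 without EG replicate 1, 2 or 3 at 18 DAP or HG replicate 2 at 28 DAP, and 4 without EG replicate 2 at 32 DAP. They were 36 without EG replicate 3 at 28 DAP, 19 without HG replicate 3 at 28 DAP and 52 without HG replicate 1 at 32 DAP.

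In integument, edgeR called 512 identifiers higher and 71 lower in HG at 32 DAP (583 called). DESeq2 called 1919, voom with quality weights 3697 and limma on FPKM 1056. On simulated counts for this comparison, falls were recovered less often than rises of the same size (11 against 20 of 40 at 4-fold, 27.5% against 50%). The 512 and 71 are therefore not a direct measure of how many identifiers differed in each direction. Whether a gap of that size accounts for the imbalance was not tested. The median log2 fold change of those higher was 3.23, and 188 of them were at least 16-fold higher. For 19 of the 512 all EG libraries had 0 counts, and with these at their bound the median was again 3.23. The leading ones had 0 counts in the 3 EG libraries: c126606_g1, with a mean of 19.1 CPM in HG (1.24 to 47.8 CPM in the 3 libraries), was at least 334-fold higher, and c43215_g1, with a mean of 17.3 CPM (0.648 to 43.9 CPM), at least 302-fold. Among those lower in HG, c74588_g1 averaged 3.19 ± 0.86 CPM against 108 ± 89.9 CPM in EG (4.24 to 167 CPM in the 3 libraries), and c128315_g1 3.30 ± 2.90 against 27.3 ± 13.8 CPM (log2 fold change -3.04, SE 0.61, edgeR adjusted p = 0.0161). As summed TMM-normalised CPM in %, the 512 identifiers together stood at 1.02%, 3.14% and 1.32% in the HG libraries and 0.272% to 0.393% in the EG libraries. In the 30 libraries of the other groups this normalised share was between 0.338% and 1.68%. It differs from a share of the raw counts by the TMM scaling of each library. Replicates 1 and 3 of HG lay within the range of the other groups, and EG replicates 2 and 3 lay below it. Among the 12 groups, EG integument at 32 DAP had the lowest mean (0.313%) and HG integument at 32 DAP the highest (1.83%). The choice of the 512 favours such extremes, and whether HG was raised or EG low was not tested. Of the 512, 457 were also higher in HG nucellus at 32 DAP, where 53% of all tested identifiers were, with a median log2 fold change of 0.97. Both lists called 3 identifiers higher in HG, among them c57814_g1, and 1 lower, c15909_g1. The normalised share of the 512 was highest in replicate 2 of HG in both tissues at 32 DAP (3.14% and 1.68%), and the comparisons in the 2 tissues cannot be taken as independent. At single stages it was not tested whether the cultivar difference differed between the tissues. The count of 583 became 0 without EG replicate 2, 3 without EG replicate 3, 6 without HG replicate 2 and 1401 without HG replicate 1. EG replicates 2 and 3 were also the most alike libraries within any group (chi-square per degree of freedom 8.41, Spearman correlation 0.983). Whether they are independent replicates was not tested. An edgeR fit of these 6 libraries alone called 0, and one without a filter on low counts 328.

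**Figure D4:**
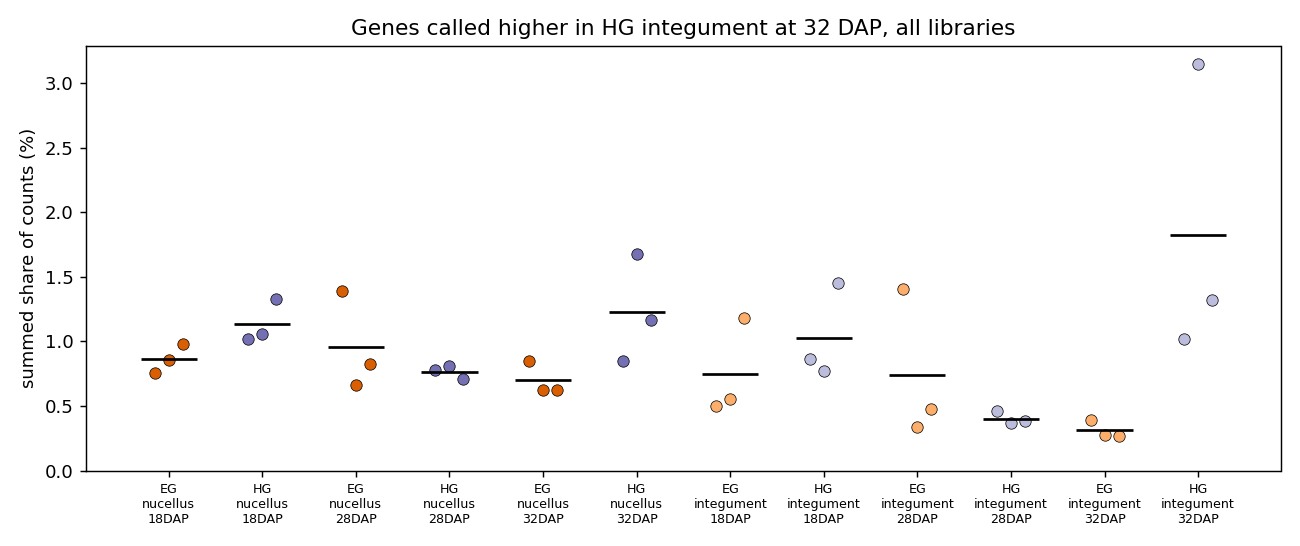
Summed TMM-normalised CPM, in %, of the 512 identifiers called higher in HG than EG integument at 32 DAP, in all 36 libraries by group on the x axis. The y axis labels this a share of counts. Points are libraries and bars are group means. The identifiers were chosen on the 6 integument libraries at 32 DAP. The 3 HG libraries lie between 1.02% and 3.14% and the 3 EG libraries between 0.272% and 0.393%. Libraries of the other groups lie between 0.338% and 1.68%.

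At 18 DAP, edgeR called 4 integument identifiers, all lower in HG, while DESeq2 called 115, voom 26 and limma on FPKM 7. EdgeR called 0 there without a filter on low counts and on the compared libraries alone, and 2 with the trend on gene length removed. Among them c7758_g1 averaged 0.456 ± 0.329 CPM in HG and 3.90 ± 0.783 CPM in EG, and c64041_g1 averaged 0.279 ± 0.0421 and 2.35 ± 0.942 CPM (SD, n = 3 each); these names, like that of c6063_g1, were chosen after the values were seen. At 28 DAP edgeR called 0, with 3841 at an unadjusted p under 0.05; DESeq2 called 32, voom with quality weights 290 and limma on FPKM 0. The mean over the stages also gave 0 calls with edgeR, with 5730 at an unadjusted p under 0.05, 272 calls by DESeq2, 755 by voom and 2 by limma on FPKM. It gave 127 without replicate 1 of EG integument at 28 DAP. The 18 DAP calls were lost without EG replicate 1 or 2 or HG replicate 2 or 3, and numbered 16 without replicate 1 of EG nucellus at 28 DAP.

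The joint test called a change of the cultivar difference between stages in integument for 217 identifiers. Another split of the libraries into cultivars gave 718 calls, so chance could not be excluded for this count. For the 217, the median log2 difference, HG minus EG, was 0.38 at 18 DAP, -2.09 at 28 DAP (-2.06 with the 10 identifiers at 0 counts in a group set to their bound) and 4.06 at 32 DAP. The median at 28 DAP rested on replicate 1 of EG, without which it was -0.46, and that at 18 DAP was 0.12, 0.19 and 1.13 without EG replicates 1, 2 and 3 and 0.62 and 0.00 without HG replicates 2 and 3. At 32 DAP it stayed between 3.23 and 4.48 with any 1 of the 6 libraries left out. The 217 were chosen with these 6 libraries included and were held fixed, so a high median there was largely set by that choice. DESeq2 called 1259 identifiers, voom 3842 and edgeR without a filter 102. Of these 217, 189 were also called between cultivars at 32 DAP. The count was 0 without EG replicate 2 or 3 at 32 DAP, 10 without HG replicate 2 at 32 DAP, and 473 and 431 without replicate 1 of EG or HG at that stage. Leaving out 1 library at 28 DAP gave 27 and 1075 for EG replicates 1 and 2, and 127, 14 and 21 for HG replicates 1, 2 and 3. In nucellus, the same test called 0 with edgeR, with 6634 at an unadjusted p under 0.05, 399 by DESeq2 and 538 by voom. It called 20 and 10 without EG replicates 2 and 3 at 28 DAP, 4 without HG replicate 1 at 32 DAP, and 1 without HG replicate 2 or 3 at 18 DAP.

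In HG integument between 28 and 32 DAP, edgeR called 296 identifiers that rose and 21 that fell. This was the highest edgeR count for a stage step within a cultivar, but the order of the steps depended on the fit. The compared libraries alone gave 2 calls here, against 360 in HG integument and 133 in HG nucellus from 18 to 28 DAP, and voom with quality weights gave 1784 against 8561 and 5081. DESeq2 called 1928 for this step and edgeR without a filter 142. The largest rises were from 0 counts at 28 DAP: c126606_g1 reached a mean of 19.1 CPM (1.24 to 47.8 CPM in the 3 libraries), at least 322-fold higher, and c44383_g1 10.9 CPM (0.177 to 25.1 CPM), at least 186-fold higher. The falls included c116206_g1, from 46.4 ± 2.83 to 16.2 ± 4.83 CPM (log2 fold change -1.52, SE 0.26, edgeR adjusted p = 0.0130), and c7693_g1, from 14.3 ± 3.53 to 4.76 ± 1.79 CPM. The count was 0, 1 and 4 without HG integument replicates 1, 2 and 3 at 28 DAP. It was 1062, 2 and 683 without replicates 1, 2 and 3 at 32 DAP, and 629 without replicate 1 of EG nucellus at 28 DAP.

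From 18 to 28 DAP, 3 identifiers rose and 7 fell in HG integument. Among them c83852_g1 rose from 13.4 ± 0.30 to 32.7 ± 1.82 CPM and c93268_g1 from 3.83 ± 1.19 to 16.8 ± 6.96 CPM, while c35172_g1 fell from 55.5 ± 40.2 to 4.07 ± 1.32 CPM and c94789_g1 from 7.31 ± 0.82 to 0.646 ± 0.365 CPM (SD, n = 3 each). DESeq2 called 915 for this step, voom 8561 and edgeR on the compared libraries alone 360. The edgeR count was 0 without replicate 3 at 18 DAP or replicate 2 or 3 at 28 DAP, 16 and 17 without replicate 1 at 18 or 28 DAP, 39 without replicate 1 of EG nucellus at 28 DAP and 37 without replicate 2 of HG integument at 32 DAP. In EG nucellus 5 rose and 5 fell over the same interval, among them c87109_g1, from a mean of 0.371 to 8.79 CPM (1.03 to 23.4 CPM in the 3 libraries at 28 DAP), c98051_g1, from a mean of 1.96 to 18.3 CPM (6.25, 6.80 and 41.9 CPM, the highest in replicate 1), c106043_g1, from 14.3 ± 8.96 to 0.839 ± 0.572 CPM, and c80321_g1, down to 3.54 ± 1.71 CPM (log2 fold change -1.82, SE 0.33, edgeR adjusted p = 0.0347). EdgeR on the compared libraries alone called 0 for this step, DESeq2 289 and voom 67. The count was 0 without replicate 1 or 2 at 18 DAP, 6 without replicate 3 at 18 DAP or replicate 1 at 28 DAP, and 287 and 283 without replicates 2 and 3 at 28 DAP.

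The other single-stage steps gave 0 calls with edgeR. At an unadjusted p under 0.05 there were 4389 identifiers for EG nucellus from 28 to 32 DAP, 7903 and 8465 for HG nucellus from 18 to 28 and 28 to 32 DAP, and 1702 and 2350 for EG integument. The EG integument numbers (2.97% and 4.10% of those tested) are fewer than independent tests without an effect would give at that threshold. The nucellus numbers (7.65%, 13.8% and 14.8%) are more. Because genes vary together across libraries, such shares can lie on either side without an effect, and they decide nothing here. DESeq2 called 150, 494, 1210, 2 and 63 in that order, and voom with quality weights 0, 5081, 2851, 0 and 1866. EG nucellus gave 615 and 387 calls without replicates 2 and 3 at 28 DAP. HG nucellus from 18 to 28 DAP gave 1228 without replicate 1 at 28 DAP, 2 without replicate 1 at 18 DAP and 36 without replicate 1 of EG nucellus at 28 DAP. From 28 to 32 DAP it gave 1126 and 609 without replicate 1 at 28 or 32 DAP, 58 without that EG library and 1 without replicate 2 of HG integument at 32 DAP. EG integument from 28 to 32 DAP gave 5 without replicate 2 at 28 DAP.

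Averaged over the cultivars, 26 nucellus identifiers rose and 27 fell from 18 to 32 DAP. In integument 7 rose and 9 fell. DESeq2 called 316 and 404 and voom with quality weights 580 and 1003 in nucellus and integument. The median absolute log2 fold change of the integument calls was 2.51. The nucellus count ranged from 11, without EG replicate 3 at 32 DAP, to 134 without replicate 1 of EG nucellus at 28 DAP. Omission of other nucellus libraries gave 21 (EG replicate 1 at 18 DAP or replicate 2 at 32 DAP), 23 (EG replicate 2 at 18 DAP), 35 and 16 (HG replicates 2 and 3 at 18 DAP) and 22 (HG replicate 2 at 32 DAP). In integument the count was 51 without HG replicate 3 at 32 DAP and 43 without replicate 1 of EG nucellus at 28 DAP. It was 9, 4 and 1 without EG replicates 1, 2 and 3 at 32 DAP, 1 without HG replicate 1 or 2 at 32 DAP, 4 without EG replicate 1 at 18 DAP and 2 without replicate 3 of EG or HG at 18 DAP.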

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

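Of the tests in this part, the library axis was conceived after the data were seen, with its prediction written before its value, and those on nucellus RNA in the HG integument libraries and on HG replicate 2 at 32 DAP were written after the result was seen. The rule that a fall shared with other left-out libraries decides nothing was also added after the values were seen. The difference between the cultivars in integument changed with the stage for 217 identifiers, and it was singled out because a cultivar effect that differs between stages was called by the joint test. Other splits of the libraries into cultivars gave up to 718 calls, and 2 of 31 splits, the real one included, gave at least 217, so chance could not be excluded for this count. A split with several times the real count points to a structure of the libraries that the groups do not describe.

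Among the 583 calls between cultivars in integument at 32 DAP are 189 of the 217, and nucellus RNA carried into the HG integument libraries could not lift an integument level above the nucellus level, yet 75% of the 512 identifiers higher in HG integument exceeded their HG nucellus mean (54.9% to 81.4% with 1 of the 6 libraries left out). The choice of the 512 on these libraries may raise that share. In EG at 18 DAP, 54 of them were nucellus-preferring and 56 integument-preferring, against 1364 and 2600 of all 57344 identifiers tested. At 28 DAP these were 55 and 66, against 1969 and 3219. Both kinds were thus more frequent among the 512, the nucellus side more so. Nucellus-preferring identifiers took 1.79% to 2.27% of the counts in HG and 1.52% to 1.58% in EG. Each set was chosen in the other cultivar, so the HG and EG values cover different identifiers and are not a like comparison. Strong nucellus markers, also chosen in the other cultivar, stood however at 0.975% to 1.78% of their nucellus level in HG integument and 0.587% to 1.63% in EG. The HG values are far below what carry-over would need, which argues against it as the whole cause. The 534 calls left once the trend on gene length was removed argue in the same way against that trend. Without HG replicate 2 only 6 calls were left, but leaving out EG replicate 2 or 3 gave 0 and 3, so the fall in calls is not specific to this library; the median log2 fold change of the 512, 3.23 with all libraries, was 2.51 without it, 3.06 and 3.09 without EG replicate 2 or 3, and 3.39 to 3.55 without another, so it fell most without HG replicate 2, which stays open as a part of the cause. A library axis that also varies within other groups stays open. With each library's score on it as a covariate, 327 calls were left, 273 of them among the 583. The median log2 fold change of the 512 fell to 2.48 (median SE 0.72 before and 0.59 after). The highest score, 3.68, was that of replicate 1 of EG nucellus at 28 DAP. Scores also differed between the groups compared (-0.50 to 1.41 in HG, -1.15 to -0.39 in EG), so the covariate may take up part of a cultivar difference. A difference between the cultivars at this stage stays open as well, as a hypothesis.

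Replicate 1 of EG nucellus at 28 DAP stood apart from its group. Integument-preferring genes chosen in HG were not raised in it, with a median log2 difference to the other replicates of -0.65 (quartiles -1.92 and 0.24). Integument RNA by itself would raise them, so the value argues against it as the whole cause. Nucellus-preferring identifiers chosen in HG also took less of its counts, 4.73% against 6.38% and 6.08% in replicates 2 and 3. A general loss of genes may therefore hide some integument RNA. Low molecular complexity, as amplification from few molecules may give, is consistent with the 3.59% of well-covered genes at 0 counts, against 0.445% in the next library. No biological explanation was tested.

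The tissue comparisons at single stages and the change from 18 to 32 DAP were chosen after seeing the data. For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real count and the highest of the other splits were 1 and 0 for cultivars in nucellus at 18 DAP, 0 and 183 at 28 DAP and 31 and 0 at 32 DAP. In integument they were 4 and 0, 0 and 0, and 583 and 0. As many calls as the real split, itself included, came from 1, 10, 1, 1, 10 and 1 splits, the 10 by construction where the count was 0. For nucellus versus integument the real count was the highest at each stage, with at most 0 in other splits of EG and 1, 82 and 1 in HG at 18, 28 and 32 DAP. For the stage steps, the real and highest other counts were 10 and 0 and then 0 and 595 in EG nucellus, 0 and 0 at both steps in HG nucellus, 0 and 0 and then 0 and 1799 in EG integument, and 10 and 0 and then 317 and 30 in HG integument. The splits with 183, 595 and 1799 calls, against real counts of 0, again point to a structure of the libraries.

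With more libraries, 30 other splits were drawn for the cultivar and tissue comparisons and 20 for the stage means. The tissue difference over the stages had 13272 calls in EG (at most 118 in other splits) and 12871 in HG (at most 2). In each, 1 of 31 splits was as high, the real one. The same held for the 9 cultivar calls in nucellus over the stages (at most 0 in the other 30 splits). For the 53 and 16 stage changes from 18 to 32 DAP in nucellus and integument (at most 0), 1 of 21 splits was as high. These are the smallest shares such draws can give, and they were not adjusted over the tests. They argue against chance for each count but do not exclude it, and the 9 calls fell to 1 with a single library left out. For the 3 tests with 0 calls the splits test nothing, since all 31 give at least 0 by construction; the highest other counts were 0 for cultivars in integument over the stages, 33 for cultivar by stage in nucellus and 0 for cultivar by tissue.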

How the results depend on the processing

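The voom fit, the filter at 5 CPM, the length trend and the omission of 2 libraries from all comparisons were chosen after seeing the data. No named identifier changed direction under any alternative run, and 138 of 565 values of named identifiers no longer passed the threshold. The naming rule required groups without overlap, which left little room for a change of direction, so its absence is no support. The tissue differences over the stages stayed within 1.5 times their counts except under the filter at 5 CPM (8171 in EG and 7840 in HG, from fewer genes tested). For the rest the cause was not tested. DESeq2 called more: for cultivars in nucellus 16, 544 and 442 at 18, 28 and 32 DAP and 362 over the stages; in integument 115, 32, 1919 and 272; for cultivar by stage 399 in nucellus and 1259 in integument; for cultivar by tissue 2. For the steps from 18 to 28 and 28 to 32 DAP it called 289 and 150 in EG nucellus, 494 and 1210 in HG nucellus, 2 and 63 in EG integument, and 915 and 1928 in HG integument. Voom with sample quality weights moved the cultivar counts in nucellus to 207 at 28 DAP, 1078 at 32 DAP and 306 over the stages, in integument to 26, 290, 3697 and 755, and cultivar by stage to 538 and 3842. Its stage steps were 67 in EG nucellus from 18 to 28 DAP, 5081 and 2851 in HG nucellus, 1866 in EG integument from 28 to 32 DAP, and 8561 and 1784 in HG integument. At single stages it called 14555 between the tissues of EG at 32 DAP and 8093 and 10997 between those of HG at 18 and 28 DAP, where DESeq2 called 4807 at 32 DAP. From 18 to 32 DAP over the cultivars DESeq2 called 316 in nucellus and 404 in integument, and voom 580 and 1003. Limma on FPKM gave 7, 21, 88 and 46 in nucellus, and 7 at 18 DAP, 1056 at 32 DAP and 2 over the stages in integument. The compared libraries alone gave 0 for cultivars in nucellus at 18 and 32 DAP, 0 in integument at 18 and 32 DAP, 0 in EG nucellus and 133 in HG nucellus from 18 to 28 DAP, and 360 and 2 for the steps of HG integument.

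Without a filter on low counts, cultivars gave 0 in nucellus at 18 DAP and 19 over the stages, 0 and 328 in integument at 18 and 32 DAP, and 1 and 102 by stage; the steps of HG nucellus gave 1 and 7, and HG integument 142 from 28 to 32 DAP. The filter at 5 CPM, which left the identifiers called at 18 DAP untested, gave 0, 3, 55 and 14 in nucellus, 0 at 18 DAP and 1 over the stages in integument, 1 for cultivar by stage in nucellus, 8 and 31 for HG nucellus, and 3152 between the tissues of HG at 18 DAP. Removing the length trend gave 20 in nucellus at 32 DAP, 2 in integument at 18 DAP, 1 in HG nucellus from 28 to 32 DAP and 6 in HG integument from 18 to 28 DAP. RLE size factors moved HG nucellus from 28 to 32 DAP to 1. The replicate block moved the nucellus cultivar count over the stages to 5, HG integument to 16 and 199 over the 2 steps, and the EG tissue counts at single stages as given above. Pairing same-numbered tissues gave 17143 for EG and 17264 for HG over the stages and 0 for cultivar by tissue. In HG, where 8 of 9 libraries correlated best with their own number, it gave 8548, 7692 and 6123 at 18, 28 and 32 DAP. With either block every other count stayed within 1.5 times that of the main fit, and counts of 0 stayed at 0. Examples are 510 for cultivars in integument at 32 DAP and 173 for cultivar by stage in integument.

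Leaving out 1 library gave 0 to 1, 0 to 497 and 0 to 276 for cultivars in nucellus at 18, 28 and 32 DAP and 1 to 56 over the stages. In integument it gave 0 to 16, 0 to 0, 0 to 1401 and 0 to 127. Cultivar by stage ranged from 0 to 20 in nucellus and 0 to 1075 in integument, cultivar by tissue from 0 to 0, and the tissue difference from 11883 to 13663 in EG and 11529 to 14897 in HG. The steps ranged from 0 to 287 and 0 to 615 in EG nucellus, 0 to 1228 and 0 to 1126 in HG nucellus, 0 to 0 and 0 to 5 in EG integument, and 0 to 39 and 0 to 1062 in HG integument. Counts were simulated at the real library sizes and estimated dispersions, with libraries independent of each other. On these, the cultivar comparison in integument at 32 DAP recovered 7.5%, 50% and 52.5% of 2-, 4- and 8-fold rises and 0% and 27.5% of falls to 0.5 and 0.25 of the level. Variation shared between genes or libraries was not simulated, so recovery and false calls in the real data may differ. Other depths or group sizes were not tested.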

Other observations

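The tests on the 21 co-varying identifiers were chosen after values of some of them had been seen. A small number of identifiers were counted in a single tissue. With no count in all 18 integument libraries, 6 identifiers had counts in at least 15 of the 18 nucellus libraries, the most abundant being c88933_g1 at 2.13 CPM, at least 230-fold higher against a floor of 3 counts over the integument libraries. In the other direction there were 15, led by c23908_g1 at 0.877 CPM, at least 91.8-fold higher. Both were named after their values were seen. The 18 libraries of nucellus and of integument did not overlap for 320 identifiers higher in nucellus and 790 higher in integument, where chance alone would separate 2.20e-08% of identifiers. For the cultivars, 0 identifiers separated all 18 HG from all 18 EG libraries in either direction, and 0 were counted in at least 15 libraries of 1 cultivar and in none of the other.

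The 21 co-varying identifiers varied together in the 2 tissues of the same replicate. Over the 18 pairs of same-numbered nucellus and integument libraries, the log2 share of counts was correlated at r = 0.747 (permutation p = 0.00048, two-sided) and rho = 0.695 (permutation p = 0.00188), both from 100000 permutations (0.00144 and 0.00282 adjusted over the 3 permutation tests on this share). Without the 2 pairs farthest from the median, r was 0.613. It was 0.722 for deviations from the group means, 0.890 within EG and 0.621 within HG. The permutations disregarded cultivar and stage, so group levels that both tissues share may make the p-values smaller. No permutation test was run on the deviations from the group means. A property of the ovules, their handling before the tissues were separated, or later processing shared by the 2 libraries may each give these values, and they cannot be told apart here. The values argue against amplification of each library by itself as the whole source. For a difference between cultivars, HG minus EG was -0.65 on the log2 scale (interval -1.71 to 0.41, exact permutation p = 0.259, adjusted 0.259, over 8000 permutations within stages), which leaves that question open. What the identifiers encode was not analysed here.

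Same-numbered nucellus and integument libraries deviated together over all tested genes, with a median r of 0.277 over the 18 pairs. With the per-library trend on gene length removed the median was 0.276 (0.0521 to 0.478), which argues against that trend. Shared ovules, trees or processing days may each give this, and no table here separates them.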
